A study of Mus musculus with 25 samples.

How the data were processed

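Gene expression was measured by RNA sequencing of dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, from 25 BXD mouse strains. The BXD strains are recombinant inbred lines bred from a cross of C57BL6/J and DBA2/J, so each strain is homozygous, at nearly every locus, for the allele of 1 of the 2 parents. Per the labels, the mice were 8 weeks old, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA v2 kit, which does not mark the strand. Each strain had 1 library. The sex of the mice and the number of animals behind a library are not given in the sources used here.

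Per the submitters' processing notes, CASAVA 1.8.0, TopHat2 2.0.9 and HTSeq were used, with the builds NCBIM37 and mm9. The deposited table held 1 column per strain and 16220 genes under Ensembl identifiers. Its unit was a normalized score: whole numbers that the values themselves showed to be read counts scaled by the authors to a common upper quartile and rounded. The third quartile over the listed genes was identical in all 25 libraries, and low values followed a regular step. The scaling tool and any filter on low genes are not given in the sources used here. Because the values were not raw counts, no model of counts was fitted. They are called scaled counts below.

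Each library's scaling factor was estimated from the step between its low values. The step was clear in 24 of 25 libraries and not in BXD36. The factors ran from 0.622 to 1.25, on a scale where the mean of 1 / factor is 1. Totals of the scaled counts ran from 24637919 to 26860283 per library. Divided by the factor, they gave an estimated 20030000 to 40150000 reads per library, with a median of 23100000. The range was 20030000 to 40150000 in the TyJ group and 21780000 to 31690000 in the RwwJ group. Counting error made up a median of 9.1% of the variance between strains. This share was 27.1% for the 3692 genes with a mean of 10 to 100, 10.7% for the 6865 genes with a mean of 100 to 1000, and 2.9% for the 5595 genes above that. No 2 libraries agreed within sampling noise: the lowest chi-square per gene between 2 libraries was 13.1, for BXD9 and BXD77.

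Symbols, biotypes, chromosomes and exon lengths came from the GENCODE release given for mouse, which describes a later build than the deposited table. It was used for names, for the chromosome of a gene and for which genes neighbour each other, and no coordinates are printed. Of the 16220 identifiers, 15697 had an entry and 523 did not. Genes without a symbol were counted and not named. Of the genes tested, 96.8% were annotated.

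The strains were grouped by the ending of the strain name in the labels, TyJ in 16 strains and RwwJ in 9. The ending is the code of the laboratories a line came from and was the only labelled difference between the mice besides the strain itself. All tests used log2(scaled count + 1) and the 16152 genes with a mean of at least 10, which left out 68 genes. Fold changes are on that log2 scale, which understates changes of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a trended prior and Benjamini-Hochberg adjustment at 0.05, two-sided. The main designs, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined.

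For genes at 2 levels, the 25 ordered log2 values of a gene were split, with at least 5 strains on each side, where the ratio of the sum of squares between the sides to that within them was largest. The p came from 1000000 simulated normal samples of 25, so 1e-06 is the smallest p it can give, and was adjusted by Benjamini-Hochberg. The sides were described by their ranges only. The spread over strains was described, without a test, by the SD of the log2 values and by the ratio of the 90th to the 10th percentile of scaled count + 1.

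The score of a gene list was the mean of log2(scaled count + 1) over its measured members. Scores were compared between TyJ and RwwJ by an exact two-sided permutation test over all 2042975 splits of the strains into 16 and 9, adjusted over 31 lists. Members were also tested with the adjustment over the list alone. The spread of a list was given as the percentile of its members' median SD among 10000 random lists of the same size matched on mean expression. The scores of the 17 lists of cell types and other tissues were correlated in 136 pairs, with Pearson's r, Spearman's rho and 100000 permutations each, so that 1e-05 is the smallest p they can give. No pooled r is given for a score treated as lying at 2 levels. The threshold for this, an unadjusted p under 0.05 in the test for 2 levels, was set after the scores were seen. It was met by 4 of the 31 lists, without adjustment over the lists, so it does not establish 2 levels for a score.

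The lists were pan-neuronal, peptidergic nociceptor, non-peptidergic nociceptor, pruriceptor, C-low-threshold mechanoreceptor, large-diameter neuron, satellite glia, myelinating Schwann cell, fibroblast and matrix, endothelium and mural, macrophage, and lymphocyte and MHC class II as cell types. Erythroid, skeletal muscle, cartilage and bone, adipose and spinal cord were lists of other tissues. Processes were regeneration-associated, immediate early, voltage-gated sodium channel, voltage-gated calcium channel, potassium and HCN channel, sensory transduction channel, analgesic target, interferon response, clock output, glucocorticoid and metallothionein, heat shock, and cholesterol synthesis genes. The last 2 lists held genes with known C57BL/6J and DBA/2J alleles, called parental alleles, and sex-linked genes.

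The rule for named genes took the 5 genes of smallest p in each direction for TyJ against RwwJ (where fewer than 3 passed), the 25 of largest SD, and the 25 calls at 2 levels of largest ratio. From each list it took up to 4 members past a test, the 2 of highest mean and the 1 of largest SD, and all measured members of the parental alleles and sex-linked lists. Some genes that the rule takes are counted but not reported here. Genes named outside this rule are marked as chosen after their values were seen.

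After the values were seen, a length slope was added for each library. It is the slope, over 12313 annotated genes with a mean of at least 100, of the library's log2 deviation from the mean of all libraries on the log2 exon length of the gene. The alternatives that use it, and those that leave out BXD21, BXD36 and BXD40, the 3 libraries of lowest slope, or BXD48 from the list differences and correlations, were chosen after seeing the data. List and gene differences with 1 strain left out at a time were also added then. The other alternatives were another pseudocount (0.1 or 5), no filter or a minimum mean of 50, quantile normalization, a repeated upper-quartile scaling, limma with array weights, a rank-sum permutation test, TyJ strains numbered 32 or less, list scores as covariates, camera for lists, mean z scores, at least 8 strains a side, a null of a t distribution with 5 degrees of freedom, a dip test, and leaving out strains.

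Each procedure was tested on simulated data. For TyJ against RwwJ over 16152 genes, limma recovered 58 of 100 genes simulated with a log2 difference of 0.5 and 90 of 100 with a difference of 1, with 9 false calls. The test for 2 levels recovered 25 of 100 genes whose levels lay 4 SDs apart and 91 of 100 at 6 SDs, with 1 false call. For list scores, 3 of 100 simulated comparisons without a difference had a p under 0.05, as had 66 of 100 with a difference of 1 SD and 98 of 100 with 2 SDs. All 15 simulated pairs with a true r of 0.8 were found, with 0 false calls among the 136 pairs. Sequence matches between pseudogenes and other transcripts were found with BLAST+ 2.17.0. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.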

Results

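The data were scaled read counts of 16220 genes in dorsal root ganglia of 25 BXD strains, with 16 strains in the TyJ group and 9 in the RwwJ group. Every strain had 1 library, so a spread between strains held the differences of genotype, animal, dissection and library together. The limma and permutation p-values for TyJ against RwwJ measure differences against that spread. For genes at separate levels, the p-values compare the ordered values of a gene with simulated normal samples. Those of the correlations come from permutations of the strains. The estimated depth was 20030000 to 40150000 reads per library. The labels state no question beyond profiling the ganglia of recombinant inbred strains. They imply a description of the variation across strains, a search for genes that follow a single locus, and the comparison of the TyJ with the RwwJ strains.

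The first comparison asked which genes varied across the strains. Most genes varied little: the median ratio of the 90th to the 10th percentile of the strains was 1.51, and the median SD was 0.246 on the log2 scale. The ratio was at least 2 for 3865 of 16152 genes (23.9%), among them 3119 of 14828 protein-coding genes, and at least 4 for 769. The 25 genes of largest SD lay near 0 in some strains and far above it in others. Of these, 17 were pseudogenes, 4 were protein-coding and 4 were not in the annotation. All 25 also lay at 2 levels by the test described further on. With the mean required to be at least 50, 1949 of 13643 genes reached a ratio of 2.

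The pseudogene with the widest spread, Gm13394 on chromosome 2, ranged from 0 to 3988 scaled counts with an SD of 5.06 on the log2 scale. H2-Ea-ps, the locus of a class II antigen-presenting chain that C57BL/6 mice do not express, ranged from 0 to 3771 (SD 4.91). Gm11223 (SD 4.71), Gm6166 (4.37), Rpsa-ps10 (4.22), Rpl3-ps1 (4.21) and Gm8420 (3.95) followed. The remaining pseudogenes of largest SD were Gm13841, Rps15a-ps8, Gm16439, Gm4204, Gm13443, Atp6v0c-ps2, Gm1840, Gm14038, Gm6969 and Gm8730, with SDs from 3.45 to 3.81. Among protein-coding genes, Eno1b, an enolase gene copy, ranged from 0 to 1292 (SD 4.62) and Tpm3-rs7, related to the tropomyosin gene Tpm3, had an SD of 3.96. The mast cell protease gene Mcpt2 ranged from 0 to 823 (SD 3.90), and Lrrc31 had an SD of 3.45. Pseudogenes and gene copies share reads with near-identical genes, so their levels are uncertain.

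Genes of all sensory neurons were among the steadiest groups. The pan-neuronal score differed by 1.41-fold between its lowest strain, BXD55, and its highest, BXD21. Tubb3, the neuronal tubulin, had a mean of 94946 ± 10386 (SD, n = 25) scaled counts and Prph, the intermediate filament peripherin, 59601 ± 7461. The median SD of the pan-neuronal genes lay at percentile 38.3 of matched random lists. Genes of the spinal cord, skeletal muscle, adipose and erythroid lists varied most. The spinal cord score spanned 142-fold between BXD73 and BXD48, and the skeletal muscle score 102-fold between BXD68 and BXD60. The adipose score spanned 17.5-fold and the erythroid score 9.08-fold, while cartilage and bone spanned 2.27-fold, less than several cell types of the ganglion. The muscle actin Acta1 ranged from 76 to 8131, the fast myosin Myh1 from 1 to 1703, the troponin Tnnt3 from 60 to 7063, and the brown fat gene Ucp1 from 2 to 554. The adipose genes Cfd and Fabp4 ranged from 193 to 3079 and from 150 to 1635. Among cartilage and bone genes, Comp ranged from 219 to 1680, Cnmd from 237 to 701 and Bglap from 0 to 127.

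Scores of the other cell types of the ganglion spanned 1.55-fold to 4.87-fold. The pruriceptor (itch neuron) score spanned 4.36-fold, from BXD16 to BXD11. In that group Sst, which encodes somatostatin, ranged from 77 to 1333 and Nppb, a natriuretic peptide gene of itch neurons, from 197 to 1736, while Osmr ranged from 801 to 1551. The lymphocyte and MHC class II score spanned 4.87-fold and the macrophage score 3.06-fold, in each case from BXD16 to BXD1. In the first list, H2-Aa ranged from 1062 to 5563, Cd74 from 1917 to 10089 and the B cell gene Ms4a1 from 12 to 359. The macrophage genes C1qa, Csf1r and Cx3cr1 ranged from 670 to 2400, from 657 to 1627 and from 76 to 599. The hemoglobin genes Hba-a1, Hbb-bs and Hba-a2 ranged from 1183 to 11221, from 3557 to 27528 and from 92 to 7437; their near-identical copies share reads. The fibroblast and matrix score spanned 2.94-fold, with Fn1 (fibronectin) from 1873 to 21426, Apod from 33416 to 107258 and Dcn from 15724 to 45422. The myelinating Schwann cell score spanned 2.42-fold, with Pmp22, a myelin protein gene of nerves, from 35159 to 75283 and Mag from 300 to 3228. The highest Mag value was in BXD48, which also had the highest values of the spinal cord list genes Mobp (2992) and Mog (1018).

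The remaining cell types spanned less. The endothelium and mural score spanned 2.32-fold, with Rgs5 at 7790 ± 1413 and Acta2 from 412 to 2954. The C-low-threshold mechanoreceptor score spanned 2.01-fold, with Th (tyrosine hydroxylase) from 2791 to 7447, Fam19a4 from 1271 to 2811 and Slc17a8 from 248 to 892. Peptidergic and non-peptidergic nociceptor scores spanned 1.96-fold and 1.79-fold, satellite glia 1.95-fold, and large-diameter neurons 1.55-fold. Within satellite glia, Fabp7 ranged from 3046 to 19877, Glul from 6984 to 19248 and Apoe from 69011 to 158163. The score and 4 of the 6 members, Glul among them, were highest in BXD48, as were all 9 genes of the spinal cord list. Mrgprb4 ranged from 89 to 555, and the neurofilament genes Nefh and Nefm of large-diameter neurons had means of 67834 ± 13768 and 70927 ± 15614. These cell type lists had percentiles of 97.9 or more among matched random lists. No test of the spread was run.

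**Figure D1:**
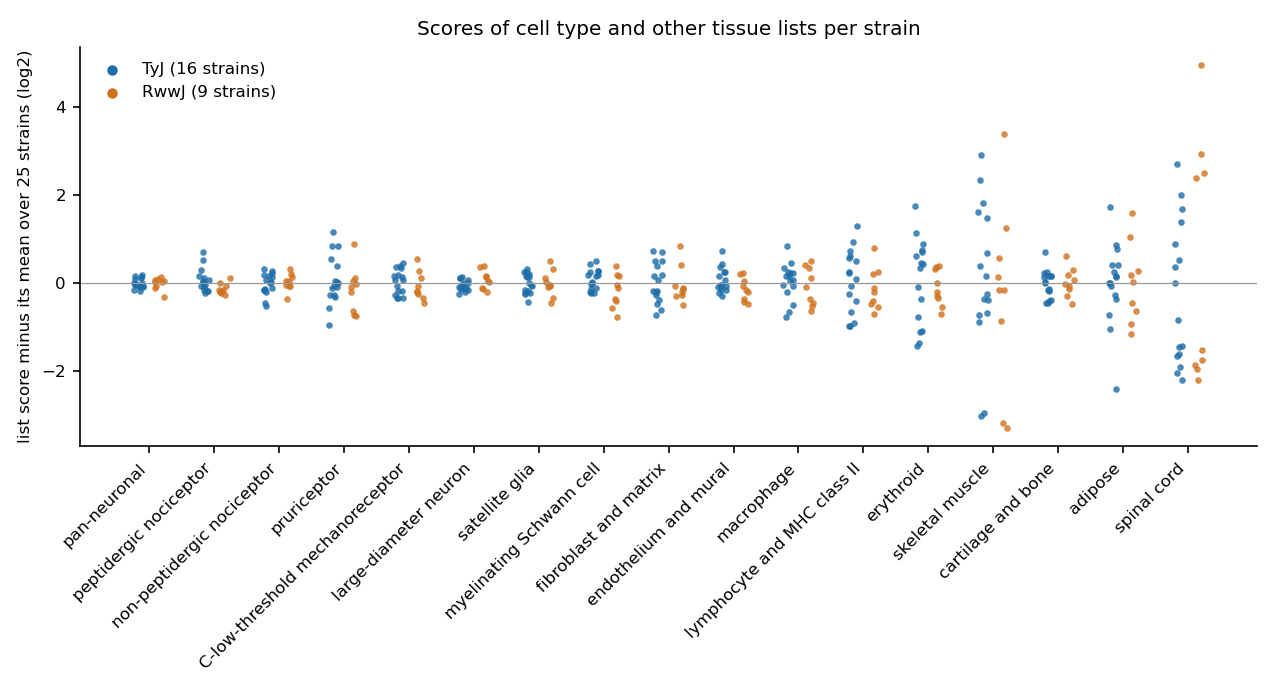
Scores of 17 lists of cell types and other tissues, each point a strain (16 TyJ in blue, 9 RwwJ in orange); the vertical axis is the list score minus its mean over the 25 strains, in log2 units. Pan-neuronal scores lie within a 1.41-fold range, while spinal cord scores span 142-fold and skeletal muscle scores 102-fold.

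The next comparison asked which genes lay at 2 separate levels across the strains, as a gene set mainly by a single locus would. There were 307 such genes among 16152 (1.9%), and in 151 of them the gap between the levels was at least 1 on the log2 scale. In 26 the lower level reached at most 10 scaled counts and the upper level began at 100 or more. The lower side held between 6 and 20 strains, with a median of 12. Of the 307 genes, 200 were protein-coding (1.35% of 14828) and 67 were pseudogenes (28.4% of 236). The odds of lying at 2 levels were 28.1 times higher for pseudogenes than for the other annotated genes (Fisher's exact test, p = 1.9e-62, with genes as the units, which are not independent).

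The genes with the clearest separation were mainly pseudogenes. Of the 25 with the largest ratio, 19 had a symbol. Gm13394 lay at 0 to 5 scaled counts in 13 strains and at 2566 to 3988 in 12. Rpsa-ps10 lay at 2 to 10 in 15 strains and at 1389 to 2197 in 10, Gm12892 at 6 to 13 in 13 strains and at 576 to 865 in 12, and Gm13841 at 0 or 1 in 17 strains and at 193 to 394 in 8. Rbpj-ps3, listed at 0 in 10 strains, lay at 20 to 34 in 15. Gm4204, Gm14038, Gm8730, Atp6v0c-ps2, Gm7658, Rpl3-ps1, Gm13328, Gm9855 and Gm8420 were pseudogenes of the same kind, and Gm7224 (0 against 14 to 41) was an unprocessed one. The others were the transcript C130046K22Rik (0 or 1 against 23 to 42), the predicted gene Gm6685 (0 or 1 against 17 to 28), the olfactory receptor gene Olfr1033 (0 against 16 to 63), and Tceanc2. Tceanc2, whose product has a domain of transcription elongation factors, lay at 60 to 109 in 13 strains and at 598 to 709 in 12. For all of these the p of 1e-06 was the smallest the simulation can give (adjusted p = 0.00012).

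The protein-coding genes Scg5, Myo7a and Tuba1c, outside the naming rule, showed the same form and were chosen after their values were seen. Scg5, which encodes a chaperone of prohormone convertase 2, lay at 2048 to 3195 in 17 strains and at 12654 to 24836 in 8. Myo7a, an unconventional myosin, lay at 61 to 101 in 12 strains and at 370 to 767 in 13. Tuba1c, an alpha-tubulin gene with near-identical relatives, lay at 124 to 338 in 18 strains and at 3073 to 4390 in 7. Mcpt2, named above for its SD, lay at 0 or 1 in 8 strains and at 144 to 823 in 17.

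At an unadjusted p under 0.05 there were 1507 genes. The count was 463 under a null with heavier tails, 97 by the dip test, and 108 after the skeletal muscle, erythroid and Schwann cell scores were regressed out, which ended the call of 11 of the 25 genes of largest ratio.

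**Figure D2:**
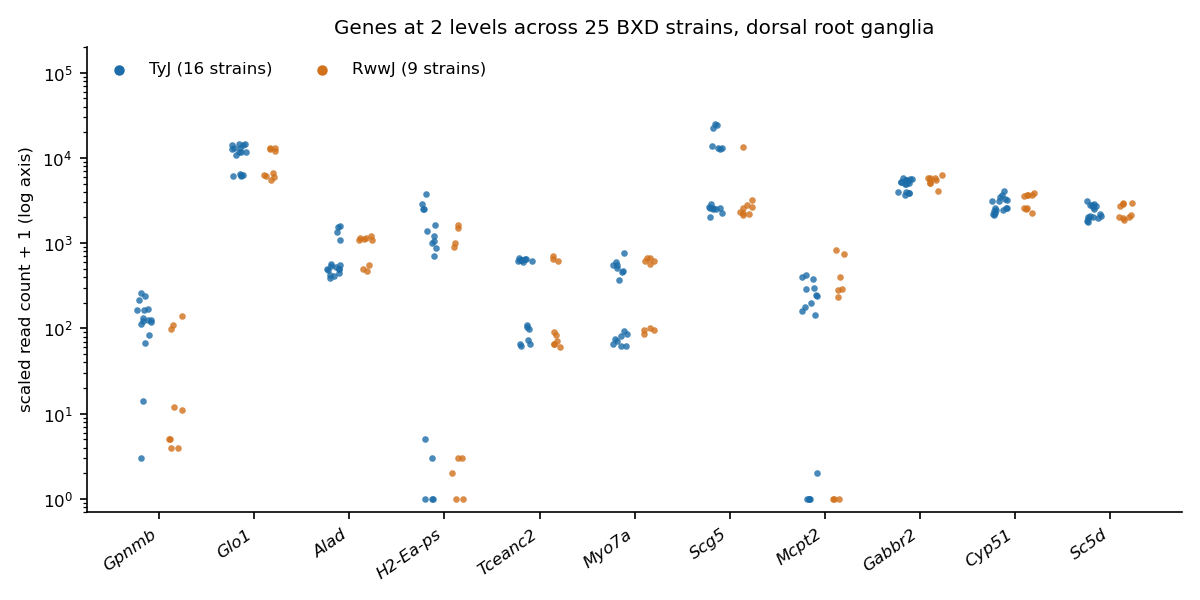
Scaled read count + 1 (log axis) of 11 genes at 2 levels, each point a strain, with the 16 TyJ strains in blue and the 9 RwwJ strains in orange. Gpnmb, Glo1, Alad and H2-Ea-ps are from the parental alleles list and both groups hold strains at each level.

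Genes with known differences between the parental strains were tested as a list. Of 14 measured members, 6 lay at 2 levels over all genes tested and 9 adjusted over the list alone. Gpnmb, a glycoprotein gene with a premature stop in DBA/2J, lay at 2 to 13 in 8 strains and at 67 to 256 in 17. Glo1, the glyoxalase gene that is duplicated in DBA/2J, lay at 5438 to 6702 in 10 strains and at 10927 to 14725 in 15. Alad, an enzyme gene of heme synthesis that is also duplicated in DBA/2J, lay at 393 to 562 in 15 strains and at 1087 to 1595 in 10. Its neighbour Hdhd3 lay at 112 to 192 and at 303 to 480, also in 15 and 10 strains. H2-Ea-ps lay at 0 to 4 in 10 strains and at 700 to 3771 in 15.

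The list-alone adjustment added 3 genes. They were the complement gene Hc (4 to 8 against 13 to 32, adjusted p = 0.0513 over all genes), the mitochondrial transhydrogenase gene Nnt (291 to 497 against 620 to 783, 0.0855) and Cox7a2l (1719 to 2406 against 2598 to 3951, 0.30). The pigment genes Tyrp1 (98 to 1333) and Myo5a (4901 to 12720), Gabra2 (292 to 1749), Ahr (201 to 463) and Kcnj9 (24 to 249) passed neither test.

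Among the other lists, 2 genes of the analgesic target list and 2 of cholesterol synthesis lay at 2 levels over all genes. Gabbr2, a subunit of the GABA-B receptor, lay at 3638 to 4112 in 6 strains and at 4974 to 6361 in 19 (adjusted p = 0.0454). Cyp51 lay at 2111 to 2617 in 13 strains and at 3093 to 4097 in 12 (0.0352), and Sc5d at 1765 to 2177 in 14 strains and at 2539 to 3149 in 11 (0.00041). Both are enzymes of the later steps of sterol synthesis. Adjusted over the list alone, the cholesterol synthesis list had 3 such genes and the analgesic target list 2. By the same adjustment the non-peptidergic nociceptor list had 2 (Ret and Mrgprx1), the glucocorticoid and metallothionein list 2 (Zbtb16 and Hif3a), and the spinal cord list 6 of 9, among them Mobp, Mog, Slc6a5 and Slc32a1. None of these further genes passed over all genes tested. No member of the lists not named here passed this test with either adjustment.

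The third comparison set the 9 RwwJ strains against the 16 TyJ strains. No gene differed after adjustment: limma called 0 genes, with 2440 at an unadjusted p under 0.05, and a rank-sum permutation test also called 0, with 2241. The genes of smallest p are given as values. They were picked by p from these same libraries, so how their libraries fall is not separate support. Cyp2j13, a cytochrome P450 gene, had 260 ± 119 scaled counts in RwwJ (SD, n = 9) and 85.0 ± 18.9 in TyJ (SD, n = 16), a log2 difference of 1.42 ± 0.25 (SE, limma adjusted p = 0.0725). It lay above every TyJ library in 7 of 9 RwwJ libraries. Cyp2j13 was also one of the protein-coding genes at 2 levels. Its group difference was not told apart from how its 2 levels fell among the strains. Gm14418 had 66.8 ± 30.7 in RwwJ and 130 ± 39.3 in TyJ, a log2 difference of -0.997 ± 0.186, and lay below every TyJ library in 7 of 9. Shpk, which phosphorylates sedoheptulose, had 334 ± 40.9 and 467 ± 73.9, a difference of -0.47 ± 0.09 (limma adjusted p = 0.0725 for both genes).

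The next in the higher direction were Nyap2 (log2 difference 0.34), Nebl (0.23), Rnf20 (0.16), a ubiquitin ligase gene acting on histone H2B, and Ttc17 (0.24), with limma adjusted p of 0.17 for Nyap2 and 0.29 for the others. Lower values were seen for Art3 (-0.52), Rapsn (-0.45), which encodes the rapsyn protein that clusters acetylcholine receptors, and Tmem59 (-0.20), each with a limma adjusted p of 0.29. Each of these 7 genes had all 9 RwwJ libraries on the same side of the TyJ mean, which picking genes by p favours. With array weights limma called 6 genes, 3 higher and 3 lower, among them Cyp2j13, Nyap2, Rnf20, Gm14418 and Shpk. Leaving out BXD48 gave 3 genes, Cyp2j13, Gm14418 and 1 without a symbol, and leaving out BXD34, BXD40, BXD55, BXD60 or BXD87 gave 1 gene each.

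**Figure D3:**
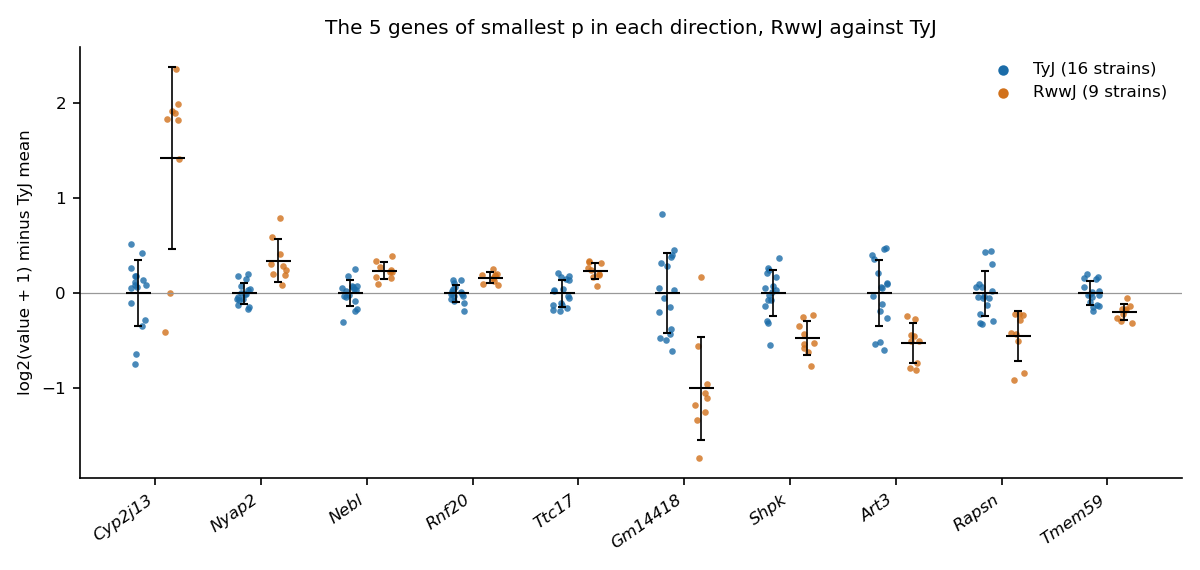
The 5 genes of smallest p in each direction for RwwJ against TyJ; points are strains (16 TyJ in blue, 9 RwwJ in orange), the vertical axis is log2(scaled count + 1) minus the TyJ mean, and bars show the mean and SD of each group. Cyp2j13 lies above every TyJ library in 7 of 9 RwwJ libraries, and 0 genes passed the limma test after adjustment.

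The gene lists were compared between the same groups. No list passed after adjustment: 0 of 31 by the exact permutation test, with 7 at an unadjusted p under 0.05 that shared an adjusted p of 0.216. With 1 strain left out at a time, the potassium and HCN channel list kept an unadjusted p under 0.05 throughout (highest 0.0405), and the highest p of the other 6 lists ran from 0.0571 to 0.137. The 3 lists of smallest p held ion channel genes, with higher scores in RwwJ. The difference was 0.19 for each of the potassium and HCN channel (exact permutation p = 0.0204), voltage-gated calcium channel (0.0235) and voltage-gated sodium channel (0.0303) lists. Without BXD21, BXD36 and BXD40 it was 0.11 (exact permutation p = 0.0625), 0.13 (0.086) and 0.13 (0.104). The mean was higher in RwwJ for 23 of 25, 12 of 14 and 11 of 12 members, and 0 of them passed limma adjusted over the list alone or over all genes, with 4 members of each list at an unadjusted p under 0.05. Examples were Scn10a, a sodium channel gene of nociceptors (0.24 ± 0.12, log2 difference ± SE), Scn7a (0.15 ± 0.08), Kcna1 (0.24 ± 0.13) and Cacna1e (0.39 ± 0.23). Cacna2d1 (-0.03 ± 0.08) and Kcnip4 (-0.06 ± 0.09) had the opposite sign. Other members named by the rule were Scn2b (0.06), Cacnb3 (0.06) and Kcnj9 (0.36). Without BXD48 the difference was 0.23 for Cacna1e, 0.12 for Kcnj9 and -0.05 for Scn2b, and without BXD55 it was 0.01 for Cacna2d1.

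Peptidergic nociceptor genes had lower scores in RwwJ, by -0.19 (exact permutation p = 0.0437), with 6 of 6 members lower. The TyJ strains BXD21, BXD40 and BXD36 had the highest scores of all strains, and without them the difference was -0.09 (exact permutation p = 0.114). Of the members, 3 passed limma adjusted over the list alone and 0 over all genes (limma adjusted p = 0.29 or more). Calca, the gene of the peptide CGRP, had a log2 difference of -0.37 ± 0.13, its paralog Calcb -0.30 ± 0.12, and Tac1, the gene of substance P, -0.35 ± 0.12. Myelinating Schwann cell genes had a difference of -0.25 (exact permutation p = 0.0487), with 13 of 14 members lower. Mal passed adjusted over the list alone (-0.40 ± 0.11), Pmp22 was at -0.25 ± 0.11, and Mag was at 0.18 ± 0.31, or -0.07 without BXD48. Interferon response genes had a difference of -0.28 (exact permutation p = 0.0467), with 13 of 14 lower. Isg15, a ubiquitin-like interferon-induced gene, passed adjusted over the list alone (-0.57 ± 0.18), while Irf7 was at -0.43 ± 0.25 and B2m at 0.04 ± 0.16. The parental alleles list differed by -0.35 (exact permutation p = 0.0488), with 8 of 14 members lower. Gpnmb passed adjusted over the list alone (-2.56 ± 0.73), and H2-Ea-ps was at -2.51 ± 1.89. Both genes lay at 2 levels, and their group differences were not told apart from how the levels fell among the strains. The mean difference of the other 12 members was 0.02. Cdkn1a (-0.22 ± 0.06) passed in the glucocorticoid and metallothionein list. No other list had a member that passed limma adjusted over the list alone, and 0 members of any list passed over all genes.

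The other 24 lists had an exact permutation p above 0.05 with all strains kept. Leaving out 1 strain took the unadjusted p under 0.05 for some of them. Without BXD48 the large-diameter neuron difference was 0.16 (exact permutation p = 0.0201). Without BXD55 the p was 0.0281 for analgesic target and 0.0444 for endothelium and mural. Differences in the cell type lists were -0.20 for endothelium and mural, 0.13 for large-diameter neurons, -0.23 for pruriceptors, -0.09 for C-low-threshold mechanoreceptors, 0.05 for non-peptidergic nociceptors, -0.01 for pan-neuronal, -0.001 for satellite glia, -0.05 for fibroblast and matrix, -0.11 for macrophages, and -0.19 for lymphocyte and MHC class II. The lists of other tissues differed by -0.17 (erythroid), -0.39 (skeletal muscle), 0.04 (cartilage and bone), 0.003 (adipose) and 0.61 (spinal cord). The spinal cord difference was 0.04 without BXD48 (exact permutation p = 0.962) and 0.93 without BXD73. The absence of BXD44, BXD77 or BXD89 moved it by over 1.5 times too. Leaving out 1 strain at a time also moved other differences by over 1.5 times. The range was -0.84 (without BXD60) to -0.01 (BXD68) for skeletal muscle, -0.27 (BXD13) to -0.06 (BXD1) for erythroid, 0.01 (BXD77) to 0.10 (BXD55) for non-peptidergic nociceptors and -0.36 (BXD48) to -0.15 (BXD73) for pruriceptors. It was -0.17 (BXD89) to -0.04 (BXD55) for C-low-threshold mechanoreceptors, -0.18 (BXD55) to -0.04 (BXD60) for macrophages, and -0.31 (BXD55) to -0.11 (BXD1) for lymphocyte and MHC class II. The process lists differed by 0.04 (regeneration-associated), -0.18 (immediate early), 0.07 (sensory transduction channel), 0.11 (analgesic target), 0.05 (clock output), -0.06 (glucocorticoid and metallothionein), -0.04 (heat shock) and 0.05 (cholesterol synthesis), and the sex-linked list by 0.06. Without BXD48 the analgesic target difference was 0.06 (exact permutation p = 0.287) and that of heat shock -0.003. Leaving out a single strain changed the sign for the pan-neuronal, satellite glia, fibroblast and matrix, cartilage and bone, adipose, regeneration-associated, clock output, and glucocorticoid and metallothionein lists. In the sensory transduction list Piezo2, the mechanically gated channel of touch neurons, was at 0.20 ± 0.09, P2rx3 at 0.08 ± 0.09 and Trpc5 at 0.72 ± 0.30 (0.54 without BXD48). With camera and the preset correlation, 8 lists passed, namely the peptidergic, Schwann cell, interferon and 3 channel lists together with endothelium and mural and immediate early. With an estimated correlation 0 passed (lowest adjusted p = 0.573).

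The channel scores moved with the length slope of the libraries, a measure added after the values were seen. The slope was computed from the same values, over genes that include list members. Slope and scores are thus not independent measures, and the permutation p does not allow for this. The labels give no RNA quality, library batch or date, so what set the slope was not tested. A technical origin of the slope, and so of the list differences that go with it, was not excluded. The slope was 0.0488 ± 0.0475 (SD, n = 9) in RwwJ and -0.0274 ± 0.0917 (SD, n = 16) in TyJ, and differed by 0.0762 (exact permutation p = 0.0301). It was lowest in BXD40 (-0.188), BXD36 (-0.178) and BXD21 (-0.150), all TyJ strains, and highest in BXD68 (0.131). Over the 25 strains and 31 lists, the slope correlated with the potassium and HCN channel score (r = 0.916, rho = 0.871, permutation p = 1e-05 for each, the smallest they can give, adjusted p = 0.00015). Without the 2 strains farthest from its median, r was 0.858. The correlation was 0.859 with the calcium channel score (rho = 0.826), 0.773 with the sodium channel score (rho = 0.652) and 0.755 with the sensory transduction score (rho = 0.802), each with an adjusted p of 0.00015. It was negative for macrophage (r = -0.648, rho = -0.699, permutation p = 0.00043, adjusted p = 0.0027), erythroid (r = -0.631, rho = -0.647, adjusted p = 0.0036), lymphocyte and MHC class II (r = -0.597, rho = -0.588, adjusted p = 0.0063) and interferon response (r = -0.582, rho = -0.551, adjusted p = 0.0083). For peptidergic nociceptors r was -0.631 (adjusted p = 0.0044) while rho was -0.382 (adjusted p = 0.12). Large-diameter neuron scores rose with the slope (r = 0.530, rho = 0.574, adjusted p = 0.018) and pruriceptor scores fell (r = -0.476, rho = -0.443, adjusted p = 0.04, and 0.064 for rho). In all, 13 of the 31 lists had an adjusted p under 0.05 for r, the others being analgesic target (r = 0.541, rho = 0.526) and sex-linked (r = 0.494, rho = 0.304). For Schwann cells r was -0.210 (permutation p = 0.31). The median exon length was 9902 bases in the calcium channel list, 7652 in the sodium channel list, 5215 in the potassium and HCN channel list, 3218 in the macrophage list and 812 in the erythroid list. The correlations did not follow that length alone. The fibroblast and matrix list, with a median of 6463 bases, had r = -0.173 (rho = -0.285, adjusted p = 0.49), and the clock output list, with 5520, had r = -0.197 (rho = -0.357, adjusted p = 0.47). With the slope as a covariate, limma called 0 genes between TyJ and RwwJ and 548 had an unadjusted p under 0.05; without BXD21, BXD36 and BXD40 it called 0, with 1231 unadjusted.

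**Figure D4:**
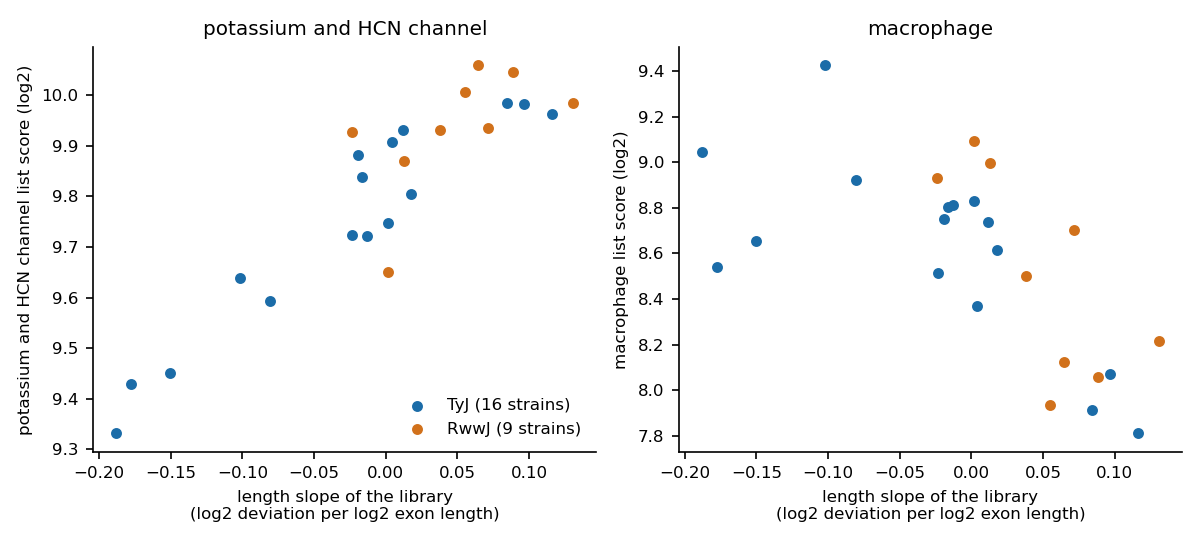
Score of the potassium and HCN channel list (left) and of the macrophage list (right), in log2 units, against the length slope of each library, in log2 deviation per log2 exon length; each point is a strain, 16 TyJ in blue and 9 RwwJ in orange. The channel score is higher in libraries of higher slope (r = 0.916), and the macrophage score is lower (r = -0.648).

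The last comparison asked which cell type and tissue scores moved together over the strains. Pan-neuronal scores ran opposite to connective tissue, vessel and macrophage scores, and the immune and blood scores ran together. Every library was scaled to a common upper quartile, so the scores are relative. The correlations therefore do not show which of 2 cell types changed in amount. Of 136 pairs, 105 had no score treated as lying at 2 levels, and 12 of these had an adjusted p under 0.05, 5 negative and 7 positive. The pan-neuronal score correlated with fibroblast and matrix at r = -0.784 (rho = -0.688, permutation p = 1e-05, the smallest they can give, adjusted p = 0.0014), with endothelium and mural at -0.650 (rho = -0.658, adjusted p = 0.0091) and with macrophage at -0.576 (rho = -0.558, adjusted p = 0.023). It correlated with the non-peptidergic nociceptor score at 0.562 (rho = 0.580, adjusted p = 0.027), and at 0.446 without the 2 farthest strains. The large-diameter neuron score correlated with satellite glia at -0.613 (rho = -0.612, adjusted p = 0.016) and with pruriceptors at -0.566 (rho = -0.548, adjusted p = 0.027). Without BXD48 these were -0.582 (adjusted p = 0.027) and -0.531 (adjusted p = 0.054). Within the 14 strains of low spinal cord score, a split used after the values were seen, that score correlated with satellite glia at 0.685 (rho = 0.609, adjusted p = 0.034, and 0.374 without the 2 farthest strains), with pruriceptors at 0.724 (rho = 0.525, adjusted p = 0.034, and 0.206 without 2) and with large-diameter neurons at -0.556 (adjusted p = 0.096). Peptidergic nociceptors also passed there (r = 0.771, rho = 0.651, adjusted p = 0.034), and 0 lists did within the other 11 strains. The large-diameter neuron and satellite glia scores themselves correlated at -0.455 within the 14 strains (rho = -0.429, permutation p = 0.1). Within the 11 strains they correlated at -0.667 (rho = -0.491, permutation p = 0.022). The sign was the same on both sides, at -0.379 and -0.334 without the 2 farthest strains. The large-diameter pairs were still not separated from the spinal cord score.

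Fibroblast and matrix, endothelium and mural, and macrophage scores correlated with each other. The r was 0.739 for fibroblast with endothelium (rho = 0.724, adjusted p = 0.002), 0.701 for endothelium with macrophage (rho = 0.736, adjusted p = 0.0034) and 0.629 for fibroblast with macrophage (rho = 0.582, adjusted p = 0.015). Macrophage, lymphocyte and erythroid scores did so too, at 0.724 for macrophage with lymphocyte and MHC class II (rho = 0.689, adjusted p = 0.002), 0.715 for macrophage with erythroid (rho = 0.587, adjusted p = 0.0034) and 0.734 for lymphocyte with erythroid (rho = 0.710, adjusted p = 0.002). Leaving out the 2 strains farthest from the median of the first list gave values from 0.576 to 0.685 for these 6 pairs. The macrophage, lymphocyte, erythroid, large-diameter neuron and, by r alone, pruriceptor scores also moved with the length slope, as given above. By rho alone, so did endothelium and mural (rho = -0.540, adjusted p = 0.017) and satellite glia (rho = -0.476, adjusted p = 0.042). With the slope regressed out of the scores, 10 pairs had an adjusted p under 0.05, and 3 of the 12 lost their call: pruriceptor with large-diameter (r = -0.421), large-diameter with satellite glia (-0.503) and macrophage with erythroid (0.518). Without BXD21, BXD36 and BXD40, 3 pairs lost their call: pan-neuronal with non-peptidergic (r = 0.474), pruriceptor with large-diameter (-0.502) and large-diameter with satellite glia (-0.546). The spinal cord and C-low-threshold mechanoreceptor scores were treated as lying at 2 levels (test for 2 levels, unadjusted p = 0.0244 and 0.0366). These p-values do not establish 2 levels. For pairs with either score no r over all strains is given, including pairs with an adjusted p under 0.05.

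The Y-linked genes Ddx3y (1183 to 1940), Uty (602 to 829), Kdm5d (199 to 392) and Eif2s3y (806 to 1242) were above 0 in all 25 libraries, and their score spanned 1.35-fold. Xist and Tsix were not analysed here.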

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

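The test in this part, a ratio of the gap at the end of a group to the group's whole range, was chosen before the results were seen. It was run in the 9 RwwJ libraries on 186 list scores, library measures and named genes. Values past the 95% critical ratio numbered 11, where chance alone gives 9.3, so their number is about that of chance. The TyJ group has too many libraries for the test. Of the 11 values, 7 came from BXD55.

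In BXD55, the voltage-gated sodium channel score was the lowest of the RwwJ libraries at 11.5, with the next at 11.9 (ratio 0.58). The potassium and HCN channel score was lowest at 9.65, with the next at 9.87 (ratio 0.538), and the sensory transduction channel score was lowest at 9.848, with the next at 10.004 (ratio 0.561). Scn10a was lowest on the log2 scale at 13.92 with the next at 14.44 (ratio 0.551), and so was Gabbr1, a subunit gene of the GABA-B receptor, at 13.10 with the next at 13.38 (ratio 0.584). The B cell gene Ms4a1 was highest at 7.26 with the next at 5.91 (ratio 0.551), and Nnt was highest at 8.96 with the next at 8.67 (ratio 0.509). BXD55 also had the lowest pan-neuronal score of all 25 strains (13.6) and the highest fibroblast and matrix score (13.6).

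In BXD48 the heat shock score was lowest at 10.6 with the next at 10.8 (ratio 0.588). In BXD89 Th was highest at 12.86 with the next at 12.24 (ratio 0.511). The pseudogene Rbpj-ps3 was listed at 0 in BXD60 among RwwJ libraries (ratio 0.882), and Gm7224 in BXD68 (ratio 0.839), and the other strains listed at 0 for these genes were TyJ strains.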

How the results depend on the processing

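The alternatives that use the length slope, or leave out BXD21, BXD36 and BXD40, or leave out BXD48 from the lists, were chosen after seeing the data. Over 108 results, 1807 of 1882 values under an alternative kept their direction and their side of the threshold, or their size where there was no test; 24 were weaker, 17 stronger, 12 moved and 22 had the opposite sign. For TyJ against RwwJ, limma called 6 genes with array weights and from 0 to 3 when 1 strain was left out, and 0 were called under the other alternatives, by limma or the rank-sum test. Limma called 3 without BXD48, and 1 each without BXD34, BXD40, BXD55, BXD60 and BXD87. With all strains of a setting kept, the unadjusted count ran from 548, with the length slope as a covariate, to 2881, with array weights. Camera with the preset correlation called 8 lists, where 0 passed with an estimated correlation. Genes at 2 levels numbered 463 with the t null (all 307 shared), 97 by the dip test (96 shared) and 108 after 3 list scores were regressed out (95 shared); they numbered 283 to 317 when 1 strain was left out, 316 after the length slope was regressed out (216 shared) and 328 without BXD21, BXD36 and BXD40 (269 shared). Of the 25 genes of largest ratio, 13 lost the call under some alternative. Genes with a ratio of at least 2 numbered 1949 with a minimum mean of 50, where 13643 genes were left, and 3297 to 3982 otherwise. Apart from the smaller number of genes that a minimum mean of 50 left, the cause was not tested. Among the values counted here, list differences of opposite sign were all small. With quantile normalization they were 0.014 for pan-neuronal and 0.032 for satellite glia. With mean z scores they were 0.079 for satellite glia, -0.053 for cartilage and bone, -0.037 for adipose and -0.077 for regeneration-associated, and with a pseudocount of 5, -0.047 for adipose. With TyJ strains numbered 32 or less they were 0.006 for pan-neuronal, 0.009 for satellite glia and 0.080 for erythroid, and without BXD21, BXD36 and BXD40, 0.029 for pan-neuronal and 0.061 for satellite glia. Without BXD48 they were 0.008 for pan-neuronal and -0.040 for regeneration-associated. In camera, with the preset and the estimated correlation alike, the mean moderated statistic of the members minus that of other genes was 0.283 for satellite glia, -0.036 for cartilage and bone, -0.024 for adipose and -0.126 for regeneration-associated. Among correlated scores, pan-neuronal with non-peptidergic lost its call with quantile normalization (r = 0.480) and pruriceptor with large-diameter with z scores (r = -0.450); after the length slope was regressed out, pruriceptor with large-diameter (r = -0.421), large-diameter with satellite glia (-0.503) and macrophage with erythroid (0.518) lost theirs, as did pruriceptor with large-diameter without BXD48 (-0.531). Depth limited genes of low counts, where counting error made up a median of 27.1% of the variance for means of 10 to 100. No paired analysis was possible because each strain had 1 library and no strain number occurred in both groups.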

Other observations

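Of the tests in this part, those on the spinal cord genes were run within each side of the score. This choice was made after the score had an unadjusted p under 0.05 in the test for 2 levels. The minimum of 3 marker genes in the pseudogene test was added after a first result. So were the interval of the r with sequencing depth and the test of depth as the whole cause. The process genes not described so far differed between single strains. BXD11 had the highest regeneration-associated score, 2.75-fold above BXD87, and the highest level of Sprr1a, an axon growth gene induced by nerve injury, at 326 scaled counts against 0 in BXD9. Gap43 (4726 to 7427) and Jun (1253 to 2544) of that list varied less. The clock output score spanned 2.81-fold from BXD1 to BXD34, with Dbp, a clock-controlled transcription factor gene, from 259 to 2005, Tef from 2081 to 4192 and Nr1d2 from 1314 to 2425. The glucocorticoid and metallothionein score spanned 2.52-fold from BXD13 to BXD5. In that list Hif3a ranged from 23 to 257, Zbtb16 from 71 to 383, Tsc22d3 from 4656 to 10185 and Mt1 from 1161 to 3170. The score had an unadjusted p of 0.00768 in the test for 2 levels, which does not establish 2 levels. The interferon response score spanned 2.55-fold from BXD68 to BXD1, and Isg15 and Irf7 were highest in BXD1 (433 and 486).

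The immediate early score spanned 2.04-fold from BXD60 to BXD42, with Nr4a1 from 609 to 1126, Dusp1 from 445 to 1508 and Npas4 from 2 to 35. Heat shock (1.70-fold, Hsp90aa1 at 30431 ± 3245, SD, n = 25, and Hspa1b from 68 to 241) and cholesterol synthesis genes (1.39-fold, Fdft1 at 8375 ± 962 and Sqle at 5778 ± 678) had the lowest percentiles of the median SD among matched random lists for the processes, 57.4 and 86.7. The analgesic target score spanned 1.74-fold, with the opioid peptide gene Pdyn from 3 in BXD34 to 175 in BXD48. BXD48 had the highest analgesic target score (8.90) and also the highest spinal cord score (9.87). The channel scores spanned 1.58-fold (sensory transduction) to 1.69-fold (sodium and calcium).

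For the pseudogenes at 2 levels, a candidate explanation is that reads of an expressed parent gene that carry the other parental allele align to a pseudogene of nearly the same sequence. Of 67 such pseudogenes, 45 matched a gene on another chromosome at 95% identity or more over at least 80% of their length, and 41 had 3 or more marker genes at both places. Apart from 2 ties, 84.6% (33 of 39, exact 95% interval 69.5 to 94.1) split the strains more like the protein-coding 2-level genes nearest the parent gene than like those nearest the pseudogene itself. The reverse held for 15.4% (5.9 to 30.5). At each place up to 5 nearest such genes on the chromosome served as markers, without a limit of distance. A weak match at the own place can therefore also come from a lack of near markers. Of the 41, 19 matched a marker at the parent in 21 or more strains and 0 did so at their own place, where random places did in 0.8%. For these 19 the values argue against the pseudogene's own place as the source. Without the minimum of markers the share was 86.0% (37 of 43), and 23 and 0 of 45 matched in 21 or more strains at the parent and at their own place. Gm13443 (10 strains low, 15 high) is 99.5% identical to Glo1 and matched one of the markers nearest Glo1 in 25 strains against 14 at its own place.

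Protein-coding genes at 2 levels were weighed next. Neighbours within 2 Mb that both lay at 2 levels split the strains alike in a median of 24 of 25 strains over 42 pairs, where the 95th percentile of random pairs on different chromosomes was 15, which is consistent with a parental allele near the gene setting its level. Poorer alignment of reads from 1 parental allele stays open: it would put linked neighbours low in the same strains, and 75% did so (24 of 32 linked pairs, exact 95% interval 56.6 to 88.5), a share on the bound set for excluding it and below the 90% set for it. The other 8 pairs lay low in opposite strains, among them Ocel1 and Colgalt1, chosen after their values were seen, which were on opposite sides in 25 of 25 strains. A hypothesis that single parental alleles set many of these levels therefore cannot be told apart from such alignment for part of the genes, since the reads and the parental genotypes were not used here.

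The spinal cord genes were weighed last, and no biological explanation was tested. In 11 strains the score lay from 5.29 to 9.87 and in 14 from 2.72 to 4.91; Mobp ranged from 15 to 2992, Slc6a11 from 53 to 3225 and Slc32a1 from 0 to 824, each highest in BXD48. Spinal cord tissue left on the dissected ganglia may explain this: of 9 other central nervous system genes 6 were measured, and their median r with the score was 0.686 within the upper 11 strains (Gpr17 0.895, Aldh1l1 0.830, Slc6a9 0.714, Nkx6-2 0.658, Bcan 0.575, Aspa -0.591), close to the 0.7 set for it, but 0.334 without the 2 farthest strains and -0.173 within the lower 14, so it stays open. The values argue against sequencing depth as the whole cause, since the depths differed by 2-fold while the highest scaled count + 1 was a median of 237 times the lowest over the 9 genes (8.47 to 825 times). A lesser trend with depth stays open: the r of the score with the log2 estimated reads was 0.111 in the upper side (95% interval -0.524 to 0.667, and 0.472 without the 2 farthest strains) and -0.178 in the lower (0.292 without 2), and 11 strains were too few to place it below the 0.4 set for excluding depth.

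For TyJ against RwwJ, chance was not excluded at an unadjusted p under 0.05. With 0 genes past the adjusted threshold, each of the 100 splits of the 25 strains into 16 and 9 has to give as many (100 of 100, the real one included, highest other 2), so that count says nothing about chance. At an unadjusted p under 0.05 the real split gave 2440 genes, 5 of 100 splits gave as many, and the highest other gave 4338, against a median of 493. Splits with that many genes point to a structure of the samples. With the length slope as a covariate, an alternative added after the values were seen, the unadjusted count was 548. In simulated data, 90 of 100 genes with a log2 difference of 1 were found. The simulated genes varied independently of each other, unlike genes in real libraries. The simulation therefore cannot settle whether the number of strains limited the real comparison. Cyp2j13, with a log2 difference of 1.42, was not called (limma adjusted p = 0.0725).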
